A study of Mus musculus with 6 samples.

How the data were processed

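Liver RNA of 8-week-old female mice was measured on 1-colour lncRNA and coding arrays of 62513 spots, with 1 array labelled for each of 3 wild-type C57BLKS/J mice and 3 C57BLKS/J db/db mice. The db/db strain carries a mutation of the leptin receptor gene and is used in the series as a model of non-alcoholic fatty liver. Per the labels' protocols, ribosomal RNA was removed, and the RNA was amplified by random priming and labelled with Cy3. The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes: background-subtracted signals and raw median signals on a linear scale, not normalized between arrays, and flags for outlier spots and for spots well above background. The authors also deposited a table of log2 values for 45318 probes. The median of each of its columns is 5.63, and the normalization and the filter behind it are not given in the sources used here. Its values lay on the log2 scale of the scanner signals, as checked by the difference between each column and each array.

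Spots with an outlier flag were removed, which left out 68 probes, and the remaining spots of a probe were averaged. Each array's log2 signal was set relative to its 75th percentile over 59709 non-control probes. A probe was tested when it was well above background on all 3 arrays of at least 1 group, where over 0.5 of a probe's spots had to carry that flag. The array's names are codes for most probes, so that 123 probes had a RefSeq accession and 116 of these matched a symbol in the NCBI gene table of assembly GRCm38.p6, which was used for names and gene neighbours only. These named 112 genes. The brightest tested probe stood for a gene, which left out 4 probes of 3 genes. All other probes stayed as probes. Probes named as lincRNA by the array, and NR accessions of lncRNA genes, were counted as non-coding.

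The arrays labelled db/db 2 and 3 differed by less than replicate spots of 1 array differ, as given with the data below. Their mean was counted as 1 sample, in place of the 3 against 3 that had been fixed before the data were examined. All tests therefore compared 3 wild-type with 2 db/db samples. The filter on dim probes still counted arrays, so that a probe could enter through 2 db/db samples but needed 3 wild-type ones. Of probes named only by a code, 25226 were well above background on all db/db arrays and 23953 on all wild-type arrays. The tested set is thus not symmetric between the groups. The design as written, with 6 separate arrays, was kept as an alternative. The labels state 3 mice in each group. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided, in R 4.3.3) and Benjamini-Hochberg adjustment over all tested genes and probes, with a threshold of 0.05. Named genes were chosen by a rule fixed before the data were examined: up to 8 increases and 8 decreases past the threshold with groups that do not overlap, the 3 smallest p-values where fewer than 3 genes passed in a direction, members of named lists, and for non-coding transcripts the 2 largest increases and the 2 largest decreases. Predicted genes and clone names were counted apart. The leptin receptor gene was to be given in every array, but no probe could be tied to it by name, and it is not analysed here. Of 33 gene lists with 579 genes, 3 genes were measured by name, at most 1 per list, which is under the minimum of 5, so that no list test was run and cell type markers are not analysed here. Probe families were tested with camera (preset correlation 0.01) after the data had been seen, with an estimated correlation as an alternative.

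A probe that was not well above background on any array of a group has only a bound there. The fold is then given as at least the difference between the brighter group's mean and the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. These bounds hold for the background-subtracted signals as scaled here and not for other background corrections. They take the brighter group's mean without its error and the dimmest probe with the flag. They are therefore not confidence limits, and "at least" is meant by this rule only. No spot was saturated. Probes well above background numbered 30147, 30392 and 30253 on the wild-type arrays and 28426, 34275 and 34025 on the arrays labelled db/db 1, 2 and 3, and the small number of samples limits the precision.

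The fit was tested on simulated data for 3 wild type against 2 db/db samples over 29516 probes, in 20 runs with 200 changed probes each. It recovered 2.0% of changes of 1 on the log2 scale, 58.7% of changes of 2, 98.9% of changes of 3 and 99.9% of changes of 4. In the same runs 10.0% of the calls were false, above the 5 in 100 that the threshold names. The real fit called 2187 of 29512, so that its cutoff on the unadjusted p was looser than in these runs. Simulated probes also varied independently of each other. These shares therefore describe the simulated setting and not the fit reported below. Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, other filters on dim probes, the replicate number and the scan session as blocks, the authors' table, another variance model, the mean of a gene's probes, other thresholds, and leaving out each array. The normexp alternative used median spot signals, since mean spot signals are not a column of the files. The 3 scan sessions of the headers took the place of slides.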

Results

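The data describe liver of 8-week-old female C57BLKS/J mice, wild type or db/db, the latter homozygous for a leptin receptor mutation and described in the series as mice with non-alcoholic fatty liver. The question was how hepatic coding and non-coding transcripts differ between these groups. The median signal per array lay between 12.4 and 24.5 intensity units, and between 47.7% and 57.5% of the non-control probes were well above background. Spots of negative-control probes were well above background in 1.33% to 11.7% of cases.

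The arrays labelled db/db 2 and 3 did not behave as separate mice. Over 24167 probes well above background on all 6 arrays, the robust SD of their log2 difference was 0.0689, against 0.564 to 0.706 in the other pairs of arrays of 1 group. Among bright probes their difference had a robust SD of 0.0529, below the 0.0605 that replicate spots of 1 array give. The pair thus differed by less than the noise between replicate spots and was counted as 1 sample, called the combined db/db sample here. By the same measure, wild type 2 lay at 0.547 from this combined sample, at 0.619 from wild type 1 and at 0.577 from wild type 3. The labels give 3 mice per group. The limma p-values and SEs below rest on 3 wild-type and 2 db/db samples. They use each probe's variance moderated toward that of all tested probes, and not the probe's own spread alone.

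**Figure D1:**
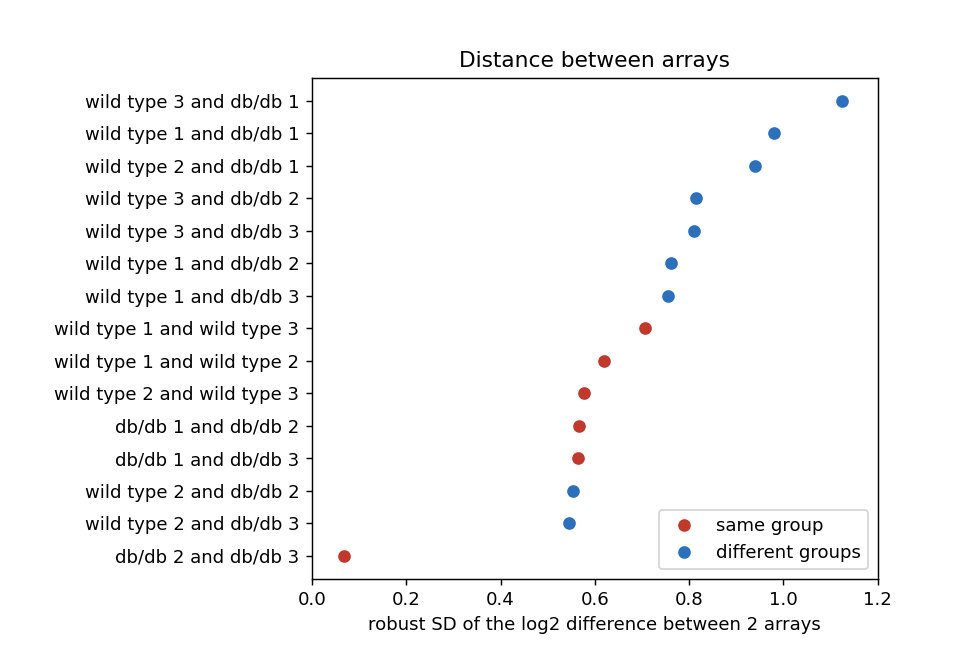
Robust SD of the log2 difference between each of the 15 pairs of arrays (horizontal axis, log2 units), over probes well above background on all 6 arrays, with pairs of 1 group in red and pairs of different groups in blue. The pair db/db 2 and 3 lies at 0.0689, the next pair of 1 group lies at 0.564, and wild type 2 lies at 0.554 and 0.545 from db/db 2 and 3.

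Liver of db/db mice differed from wild type in 2187 of 29512 tested genes and probes (limma, adjusted p under 0.05), of which 1222 were higher and 965 were lower. Each of these had a fitted difference of at least 2-fold, with a median log2 difference of 2.05 among increases and -2.34 among decreases. With a median SE of 0.40 over the tested genes and probes, the smallest log2 difference that passed was 1.35. These sizes thus partly reflect the threshold, which smaller changes could hardly pass. Fitted differences above 8-fold numbered 191 increases and 218 decreases. Of the increases, 257 were not well above background on any wild-type array, and of the decreases 216 were not well above background on any db/db array, so that their fitted values are not measured folds. Most calls, 2026, were probes that the array names only by a code, and no gene is assigned to them here. The groups did not overlap in 47.4% of the tested genes and probes, where interchangeable samples would give 20%. This is not a test of the group difference, since the filter chose probes by group and probes share shifts of whole arrays.

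The median log2 difference over all tested genes and probes was 0.17, and it was 0.06 after quantile normalization and -0.04 with the percentile taken over probes detected on all arrays. The difference was larger among bright probes: among 2320 genes and probes with a mean log2 signal above 6, the median difference was 0.56 and 83.4% were positive, against 0.06 and 55.4% after quantile normalization. Of the calls, 55.9% were increases in the fit given here, 39.5% with the percentile over probes detected on all arrays, and 66.9% after normexp background correction, where 1326 of the 2187 calls were shared. Without the combined db/db sample 31% of 987 calls were increases. Without db/db 1, which leaves 1 db/db sample assumed to vary like the wild type, 117 genes and probes passed. Arrays were scanned in 3 sessions, and only 1 of them held both groups, with wild type 1 and 2 and db/db 3. With the session as a block, where db/db 3 is the only db/db array that enters the contrast and the spread comes from wild type 1 and 2 alone, 507 increases and 433 decreases passed.

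**Figure D2:**
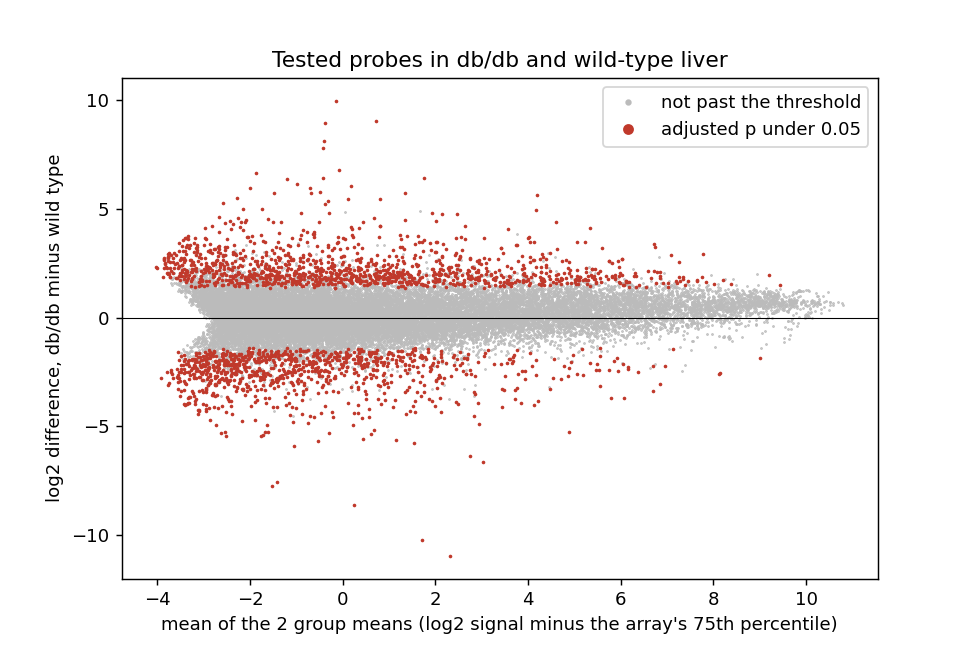
Log2 difference, db/db minus wild type, of 29512 tested genes and probes (vertical axis) against the mean of the group means (horizontal axis, log2 signal relative to the array's 75th percentile). Red points are the 2187 with adjusted p under 0.05, 1222 above and 965 below 0.

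Among 62 genes measured by name, 4 were higher in db/db liver past the threshold, adjusted over all genes and probes tested, and 0 were lower. Over all tested genes and probes 7.41% passed. At an unadjusted p under 0.05, 21 named genes were higher and 2 lower in limma, where 7848 of all 29512 genes and probes had such a p. Of the 62 named genes 44 had a positive difference, with a median of 0.52 on the log2 scale against 0.17 over all. The balance of 21 to 2 thus lies on an upward offset of the named genes. Hhipl2, a gene related to the hedgehog-interacting protein gene, rose at least 4.2-fold (limma adjusted p = 0.00649), and was not well above background on any wild-type array. Tfrc, the transferrin receptor that takes up iron into cells, rose by 2.06 ± 0.43 (SE) on the log2 scale, or 4.18-fold, from 3.74 ± 0.62 (SD, n = 3) to 5.81 ± 0.13 (SD, n = 2), with a limma adjusted p of 0.0257. Disp1, which releases hedgehog ligands from producing cells, rose by 2.10 ± 0.44 (SE), with a limma adjusted p of 0.0260. Fam177a2 rose by 1.40 ± 0.35 (SE), with a limma adjusted p of 0.0442. Relative to the median of all tested genes and probes, the log2 differences of Tfrc, Disp1 and Fam177a2 were 1.89, 1.92 and 1.22, and relative to genes and probes of like brightness they were 1.78, 2.08 and 1.38.

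Several settings ended these 4 calls. Without db/db 1 none passed. With 1 db/db sample left, the SEs were larger: Tfrc differed by 1.97 ± 0.59 (SE), Disp1 by 1.68 ± 0.54 and Fam177a2 by 1.28 ± 0.45 (limma adjusted p = 0.282, 0.336 and 0.379), and Hhipl2 was at least 3.22-fold higher (0.141). None passed without a filter on dim probes, which leaves each difference as it is and tests 59637 genes and probes (limma adjusted p = 0.0613 for Hhipl2, 0.140 for Tfrc, 0.142 for Disp1 and 0.194 for Fam177a2), and none with the replicate block that takes the combined sample as number 2 (0.0695, 0.0990, 0.0911 and 0.110). After normexp background correction Hhipl2 differed by 0.94 on the log2 scale, below the bound given above, and did not pass (limma adjusted p = 0.0601). Tfrc and Fam177a2 did not pass after quantile normalization (limma adjusted p = 0.0546 and 0.0541), and Tfrc, Disp1 and Fam177a2 did not pass without the combined sample, with log2 differences of 2.15, 2.51 and 1.51 (0.0952, 0.0585 and 0.114). Fam177a2 also did not pass with the replicate block that takes the combined sample as number 3 (limma adjusted p = 0.0567), with median centring (0.0637), with the percentile over probes detected on all arrays (0.0725), with the authors' table (0.0553), or without wild type 1, 2 or 3 (0.0667, 0.0748 and 0.0626). With the scan session as a block the contrast rests on wild type 1 and 2 against the single array db/db 3. The log2 differences of Tfrc, Disp1 and Fam177a2 were then 1.95, 1.42 and 1.29. The fitted difference of Hhipl2 was 2.48, which is not a measured fold, as it was not well above background in wild type. The variance in this fit came from these 2 wild-type arrays and was largely pooled over probes.

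**Figure D3:**
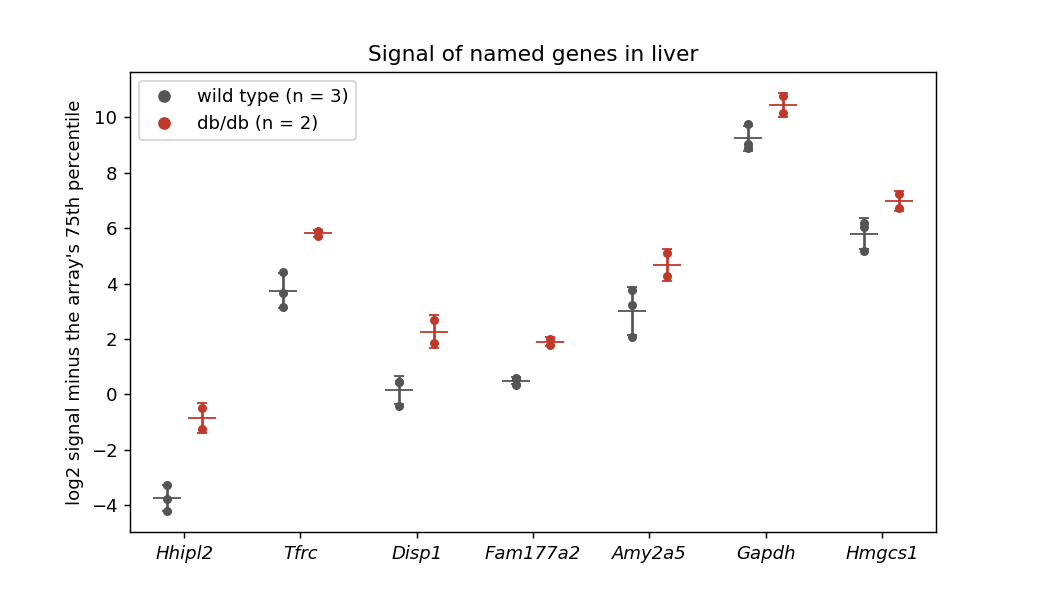
Signal of 7 named genes in liver (vertical axis, log2 signal relative to the array's 75th percentile), with a point per sample, the mean as a dash and the SD as a bar, for 3 wild-type samples and 2 db/db samples. Tfrc lies at 3.74 in wild type and 5.81 in db/db on average, Hhipl2 was not well above background on any wild-type array, and Amy2a5, Gapdh and Hmgcs1 did not pass the threshold.

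With predicted genes counted apart, which leaves out Gm4312 (log2 difference -1.02, limma adjusted p = 0.123), the smallest p-values among lower genes were those of AY761185, Jrkl and Tbp, with log2 differences of -1.22, -0.89 and -0.73 and limma adjusted p of 0.0763, 0.241 and 0.254, none past the threshold. Without db/db 1 the differences of Jrkl and Tbp were -0.42 and -0.44, and with the scan session as a block they were -0.55 and -0.28. Without the combined sample Jrkl differed by -1.37, and after normexp background correction AY761185 differed by -0.25. With 6 arrays as separate samples, where 1 sample counts as 2, AY761185 and Gm4312 passed (limma adjusted p = 0.0221 and 0.0348). In the lists fixed beforehand, 3 genes had a named probe and none passed. Hmgcs1, the cytosolic synthase that feeds cholesterol synthesis, differed by 1.17 ± 0.43 (SE) with a limma adjusted p of 0.122. Gapdh of glycolysis differed by 1.21 ± 0.41 (SE) with a limma adjusted p of 0.105, and it passed after normexp background correction (0.0323), a setting that ended the call of Hhipl2. After quantile normalization, which removed most of the shift of bright probes, the differences of Hmgcs1 and Gapdh were 0.76 and 0.61. Amy2a5, a pancreatic amylase gene, differed by 1.66 ± 0.53 (SE) with a limma adjusted p of 0.0902. It passed without wild type 2, with a difference of 2.03 (limma adjusted p = 0.0442), with the replicate block that takes the combined sample as number 3 (0.0145), and with 6 arrays and the replicate block (0.0425). Hmgcs1 passed with 6 arrays and the replicate block (limma adjusted p = 0.0491). With the scan session as a block the differences of Amy2a5 and Hmgcs1 were 0.76 and 0.60, neither past the threshold, and with the authors' table that of Hmgcs1 was 0.75. Ppp2r3d, named here after its values were seen, had probes with differences of one direction that fell on both sides of the threshold: the brightest differed by 1.22 ± 0.38 (SE, limma adjusted p = 0.0809) and the other two by 1.57 ± 0.38 and 1.52 ± 0.35 (0.0417 and 0.0347 over all tested probes). The mean of its probes passed (limma adjusted p = 0.0464), and the brightest differed by 0.71 after normexp background correction and passed with 6 arrays (0.0228). Probes of Ccl21b, Ccl21c and Gm13304 belong to near-identical gene copies, and their values of 1.21, 1.00 and 1.27 cannot be assigned to a single copy. None of these 3 passed in the fit given here, and each passed with 6 arrays as separate samples (limma adjusted p = 0.0341, 0.0417 and 0.0339).

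Non-coding probes changed in both directions. Of 1729 tested, 58 were higher and 49 lower in db/db liver (limma, adjusted p under 0.05), which is 6.19% against 7.49% of the other genes and probes (Fisher's exact test, p = 0.0468, adjusted p = 0.187 over 8 sets of probes). These others are not a coding set. They include 26967 probes named only by a code, whose type is not known here, and 214 probes of ultraconserved regions. The array's non-coding transcripts are therefore counted only in part. The lincRNA exon probe 10679 on the minus strand rose at least 10.5-fold (limma adjusted p = 0.000244), with a signal not well above background on any wild-type array. Without db/db 1 this bound was 8.73-fold. The exon probe 11433 on the minus strand rose by 4.81 ± 0.47 (SE) on the log2 scale (limma adjusted p = 0.00108), and 2 of 3 wild-type arrays measured it. Its difference was 2.96 after normexp background correction, past the threshold. It was 4.05 without db/db 1 and 3.91 with the scan session as a block, 2 fits with a single db/db sample in the contrast, whose spread comes from the wild type alone. The exon probe 11429 on the minus strand was at least 31.6-fold lower in db/db (limma adjusted p = 0.000681), and the mouse lincRNA probe 0294 was at least 3.25-fold lower (limma adjusted p = 0.00294). After normexp background correction the differences of probes 10679, 11429 and 0294 were 1.89, -2.90 and -0.77 on the log2 scale, all smaller than the bounds given here, and 0294 did not pass (limma adjusted p = 0.129). Without db/db 1 probe 0294 was at least 4.27-fold lower and did not pass (limma adjusted p = 0.0556), with an SE of 0.63 against 0.49 with both db/db samples. Without db/db 1, 6 non-coding probes passed, and with the scan session as a block 52 passed. Camera found no family of probes shifted against the rest, with the smallest adjusted p of 0.270 for probes with custom accessions and 0.894 with an estimated correlation.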

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

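Counts of increases and decreases were 1222 and 965 as reported. They were 666 increases (1355 calls in all, 68 of them non-coding) with quantile normalization, and 737 increases with the authors' table. After normexp background correction 66.9% of 2283 calls were increases, and 1326 were shared with the 2187 reported. Without a filter on dim probes they were 116 and 120 (236 in all, 12 non-coding), and with probes well above background on all 6 arrays 70 non-coding probes passed. At an adjusted p under 0.1 they were 2539 and 1786 (4325 in all, 203 non-coding), and under 0.01 they were 258 and 243 (501 in all, 24 non-coding). With the scan session as a block they were 507 and 433 (940 in all, 52 non-coding). The cause of these shifts was not tested, apart from the threshold itself.

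The replicate block with the combined sample as number 3, and that with 6 arrays, were chosen after seeing the data. The replicate block with the combined sample as number 2 had been planned. The fit of 6 arrays as separate samples was the main fit fixed beforehand, made an alternative once the data were seen. With the replicate block, 250 and 313 passed (563 in all, 34 non-coding) with the combined sample as number 2, and 2077 increases (3513 in all) with it as number 3. Deviations from the group means correlated at 0.18, 0.07 and 0.12 for arrays with numbers 1, 2 and 3. With 1 combined sample the deviations of db/db 1 mirror those of db/db 2 and 3, so these are not independent pairs and cannot settle whether the numbers pair the samples. The labels give no shared litter or batch. With 6 arrays as separate samples, 2942 and 1806 passed (4382 at 2-fold or more, 229 non-coding), and with 6 arrays and the replicate block 2566 and 1865 (4391 at 2-fold or more, 216 non-coding), where 1 sample counts as 2.

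Leaving out 1 array or sample at a time gave 48 to 1338 increases and 69 to 1195 decreases, 117 to 2528 calls and 6 to 115 non-coding probes. The low ends came without db/db 1, and without both scans of the combined sample 306 increases (987 in all, 35 non-coding) passed. Of the comparisons of named genes and probes with an alternative, 510 kept their side of the threshold, 42 no longer passed and 25 newly passed, and 0 changed direction. Leaving out a sample could not turn a called difference, since the groups did not overlap in any of the 2187 calls. The lists' camera and fry alternatives were not run, because no list had 5 members. Signal over background limits the dim probes: 257 increases and 216 decreases rest on a group with no array well above background.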

Other observations

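The tests in this part were chosen only after the results were seen. Of 214 tested probes of ultraconserved regions, stretches of DNA identical between distant mammals, 4 were higher and 12 lower in db/db liver (limma, adjusted p under 0.05), a 25% share of increases against 56.1% among other calls (Fisher's exact test, p = 0.0200, adjusted p = 0.0400 over the 2 families tested). The share was 30% against 49.3% after quantile normalization (3 higher and 7 lower, Fisher's exact test, p = 0.343) and 25% against 50.1% after median centring (3 and 9, p = 0.145). It was 11.1% against 39.8% with the percentile over probes detected on all arrays (2 and 16, Fisher's exact test, p = 0.0139), so that the share lay below that of other calls under these 4 scalings, with p under 0.05 in 2 of them. This describes the called probes and not the family: over all 214 probes the median log2 difference was 0.17, as over all tested genes and probes, and camera found no shift against the rest (p = 0.384, adjusted p = 0.645 over 8 sets of probes, and p = 0.581 with an estimated correlation). The balance is also not particular to ultraconserved regions. Of human lincRNA probes, 5 were higher and 12 lower past the threshold, and their direction was not tested. The other families had more increases than decreases. The adjustment over 2 families does not cover the choice among these sets of probes. The plus-strand probes of regions uc.26 and uc.420 rose by 2.44 ± 0.48 and 2.29 ± 0.40 (SE) on the log2 scale (limma adjusted p = 0.0209 and 0.0131). The plus-strand probe of uc.353 was at least 3.11-fold lower (limma adjusted p = 0.00258), and that of uc.83 fell by 3.20 ± 0.42 (SE) (limma adjusted p = 0.00396). Without db/db 1 none of these 4 calls passed. With 1 db/db sample left, the SEs were larger: uc.26 differed by 2.18 ± 0.65 (SE), uc.420 by 2.46 ± 0.53 and uc.83 by -3.59 ± 0.51 (limma adjusted p = 0.282, 0.145 and 0.0550), and uc.353 was at least 4.09-fold lower (0.0678). After normexp background correction uc.353 differed by -0.72 on the log2 scale, smaller than its bound, and did not pass (limma adjusted p = 0.166), while uc.26 and uc.420 passed with differences of 1.13 and 1.43. Neither of these passed without a filter on dim probes (limma adjusted p = 0.124 and 0.0935), without the combined db/db sample (0.0730 and 0.0800), or with the replicate block that takes it as number 2 (0.105 and 0.0802). With the scan session as a block, which rests on the single array db/db 3, uc.26 did not pass (limma adjusted p = 0.113).

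Sly and Ssty2 are genes of the Y chromosome, and the mice were female. Their probes were well above background on all 6 arrays, a flag that 1.33% to 11.7% of negative-control spots also carried, depending on the array. Both were dim, with group means between -2.42 and -0.85 relative to the 75th percentile. Whether these probes measured the named genes was not tested, so the flags do not show expression from a Y chromosome. Sly differed by 1.41 ± 0.38 (SE) on the log2 scale (limma adjusted p = 0.0547), and it passed with probes well above background on all 6 arrays (0.0391) and with 6 arrays as separate samples (0.0212), while after normexp background correction it differed by 0.62. Ssty2 differed by -0.97 ± 0.59 (SE) (limma adjusted p = 0.320), a value that single samples moved: it was -0.42 without wild type 1, -1.57 without db/db 1 and -0.36 without the combined sample. It was -1.73 with the scan session as a block and -0.27 after normexp background correction, and it passed with 6 arrays and the replicate block (-1.17, limma adjusted p = 0.0405).

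The arrays labelled db/db 2 and 3 may be 1 array scanned in 2 sessions. Deviations of single negative-control spots, which belong to the physical array, correlated at Spearman's rho of 0.607 over 1200 spots, across spots of 1 pair of arrays, against at most 0.189 in the other 14 pairs. Against 1 RNA sample on 2 arrays, 4 spots were marked as non-uniform on both, with 0 such spots in any other pair and 0.00128 given by chance. Against 2 mice with similar livers, the robust SD of their log2 difference was 0.0689, where the closest other pair of 1 group had 0.564. Which mouse the array came from, and whether another file was meant to stand for db/db 3, stays open.

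In the authors' table, the columns of db/db 2 and 3 may be exchanged relative to the scanner files. The SD of the difference between table column 2 and array 3 was 0.0417, and between table column 2 and array 2 it was 0.111. The other 4 columns lay closest to their own arrays. Whether the table or the scanner files carry the wrong label was not tested, and the mean of both columns used here is the same either way.

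Among the 2187 calls, 75% had a larger difference from wild type in db/db 1 than in the combined db/db sample, with medians of 2.40 and 1.91 on the log2 scale. The ratio of signal SDs, db/db 1 over the combined sample, was 1.04, and that of these medians was 1.25. A wider signal range on the array of db/db 1 would also change its differences from wild type, by an amount that depends on a probe's brightness. The ratios need not match, so they do not decide on this explanation. A scan session effect would leave db/db 1 and db/db 2, both of 1 session, with like medians, and the ratio of their medians over these calls was 1.26. That of db/db 2 over db/db 3, of 2 sessions, was 0.992. Mice that differ in the size of the change stay open as an untested explanation, since each value rests on 1 sample, and the 117 calls without db/db 1 may in part come from having fewer samples.

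Of the 10 splits of the 5 samples into 3 and 2, 1 gave as many calls, the real one with 2187, and the highest other split gave 4. With 10 splits the share cannot fall under 0.05.

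Hhipl2 and Disp1 lie near each other in the gene order of GRCm38.p6, with Brox, Aida, Mia3 and Taf1a between them, and a candidate explanation is that neighbouring genes shift together. Brox, Aida and Taf1a had log2 differences of 1.01, 1.53 and 0.39, none past the threshold, and 0.65, 0.80 and 0.15 with the scan session as a block, and Mia3 was not tested. Aida passed with the replicate block that takes the combined sample as number 3 (limma adjusted p = 0.0311), and Brox with 6 arrays as separate samples (0.0487). Their median of 1.01 was reached by a share of 0.108 of 10000 random sets of named genes that did not pass, so that these values do not decide it.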
